A study of Nitratidesulfovibrio vulgaris with 4 samples.

How the data were processed

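Cultures of Nitratidesulfovibrio (Desulfovibrio) vulgaris Hildenborough were exposed to CuO nanoparticles at 1, 50 or 250 mg/L for 24 h, with an unexposed control. Per the labels' protocols, RNA was extracted with a QIAGEN miRNeasy kit after bead-beating and treated with DNase, and Illumina libraries were made. Each of the 4 groups has 1 library, so no test between groups was made and no p-value was computed.

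The expression values are RPKM, per the file headers, in 3 deposited tables that each set a dose beside the control. Cufflinks 2.2.1 is named in the submitters' processing notes. The aligner, the genome build, the strand setting and the normalization between libraries are not given in the sources used here. The authors' p-values and q-values come from the same deposited tables; with 1 library per group they rest on the authors' assumption about the spread and are quoted as theirs. The authors' log2 fold changes in the deposited tables were not used, and ratios were recomputed from the RPKM values. The control values were identical in the 3 tables (0 differences). The 50 mg/L table holds a further block that compares 50 with 1 mg/L, with 52 authors' calls at q of 0.05 or less in the authors' deposited table, and its values equal those of the 1 mg/L library (0 differences). Columns of per-sample values that match no sample numbered 0. Where an RPKM normalization holds totals fixed, a large rise of abundant genes lowers the values of all others, so ratios were also computed with other scalings.

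Each table holds 3481 genes. The 86 rows of structural RNA are all listed at 0, so the share of ribosomal RNA cannot be given, and they were left out. The authors' locus holds 1 gene for 2448 rows and 2 or more for 1033, in which the division of reads is uncertain. Sequencing depth is unknown, so no interval or floor is given, and a gene at 0 is only said to be listed at 0. Of the rows, 2695 carry a locus tag as name, 474 symbols were matched to a tag by position and 129 by symbol, and 183 have no tag, of which 97 are not structural RNA. The reference, NCBI assembly ASM19575v1, served for names only; at 1268 of 1268 positions shared with tag-named genes the tags were identical. The deposited function annotation is filled only for genes at least 2-fold from the control (86, 255 and 321 genes at 1, 50 and 250 mg/L), so it depends on the outcome.

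A log2 ratio was computed per gene as log2 of (treated + 1) over (control + 1), in RPKM. A gene counted as higher or lower when the ratio was at least 2-fold and either library had 10 RPKM or more. The groups, these limits, the locus tags and product wording of the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, the genes named were drawn in each comparison from the 12 highest and 12 lowest genes with a stated function among those past 2-fold, the genes of sulfate reduction and of the path from lactate to acetate, and the 4 members of each other list farthest from the control. Passed over, as hypothetical or without any deposited annotation, were 40 higher and 32 lower genes at 1 mg/L, 16 and 30 at 50 mg/L and 23 and 21 at 250 mg/L. These counts run to the last gene with a stated function that was taken. Not all of them are given in the text. A gene that the rule gives in one comparison is also followed in the others. Genes outside the rule are marked as chosen after their values were seen.

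For each of 18 gene lists, the median log2 ratio of the members was placed among 10000 random lists of the same size matched on deciles of mean expression. This percentile describes these libraries and is not a p-value. Random lists were drawn gene by gene, whereas members of some lists are neighbours on the chromosome and may vary together. An extreme percentile may therefore overstate how far such a list stands apart. To remove a trend with coding length, the running median over 101 genes nearest in length was subtracted from each gene alone in its locus. Where under 80% of a list had such a length, the members without one were set to the extreme least favourable to the pattern, and the median over all members was compared with the random lists. The iron uptake, sulfate reduction, lactate, hydrogenase, formate dehydrogenase, ATP synthase and electron transfer lists were fixed by locus tag. The others had been fixed by product wording, but the reference as used here held no product names and the deposited annotation depends on the outcome. Their members were therefore taken by gene symbol, with symbol patterns written after the tables and the authors' significant genes had been seen, and corrected by the fixed wording after the values had been seen. The oxidative stress and metal lists combine fixed tags with such symbols. The wording that some tag-fixed members also had to match could not be applied. Members of the tag-fixed lists with no matched tag, such as poR in the lactate list and cooF and hynB-2 among the hydrogenases, were taken by symbol. The flagellins carry no symbol and are not in the flagella list. Other genes that the symbol patterns do not reach are missing too. Among them are chemoreceptor genes from the chemotaxis list, DVU0307 and DVU1445 from the flagella list and DVU2800 from the metal list. Lists of multidrug efflux, phage genes, transposases and the megaplasmid were not analysed here. The design had expected FPKM; the same limits were applied to RPKM.

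Because all doses share the control, overlaps and correlations were set beside simulated libraries without effects (100 data sets). Noise was resampled within expression deciles from the ratios of 1 mg/L to the control, divided by the root of 2. Depth is unknown, so no counts were simulated, and any effect of 1 mg/L counts as noise. This version replaced an earlier one with normal noise, which lacked the heavy tails of the data and gave no overlap. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 50 RPKM, centring on the median gene, rescaling to equal library sums, a 3-fold limit, the mean over list members, steps of 1.2-fold and a q of 0.01. Added after the data had been seen were counts without genes listed at 0, with genes alone in their locus, and with those of at least 300 bases.

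The steps were tested on simulated data with known differences in 200 genes. At a set difference of 3-fold, 98.8%, 97.0% and 98.4% of genes were called in the simulations of 1, 50 and 250 mg/L (2873, 2876 and 2876 genes), and at 6-fold 98.3%, 98.5% and 100.0%. At 1.5-fold 1.69%, 1.52% and 3.03% were called in the set direction, with 1 further gene called in the wrong direction at 1 and at 50 mg/L and 0 at 250 mg/L, and of unchanged genes 3.14%, 3.18% and 3.25%. The noise in all 3 simulations was the ratios of 1 mg/L to the control, shuffled within expression deciles. The unchanged rates thus follow from the 2.97% of genes past 2-fold at 1 mg/L. They give no rate of false calls for 50 or 250 mg/L. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.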

Results

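RNA was measured in cultures of Nitratidesulfovibrio (Desulfovibrio) vulgaris Hildenborough, a strictly anaerobic bacterium that respires sulfate and oxidises lactate. Cultures in a defined medium with lactate and sulfate received copper oxide (CuO) nanoparticles at 1, 50 or 250 mg/L for 24 h, and a control culture received none. The 4 libraries stood for 4 groups, with 1 library per group, so no difference given here has a replicate check and none was tested. The question was which genes differ in RNA level with the dose of the nanoparticles. Values were RPKM (reads per kilobase of gene, scaled to library size) as deposited, for 3481 genes of the chromosome. Sequencing depth is unknown from these values, so no counting interval is given. Summed RPKM was 443305 in the control, 444651 at 1 mg/L, 504322 at 50 mg/L and 575983 at 250 mg/L, while the median gene, structural RNA left out, lay at 45.1, 44.7, 44.0 and 46.8 RPKM. The 10 most abundant genes took 13.8% of the sum in the control, 12.3% at 1 mg/L, 16.0% at 50 mg/L and 16.4% at 250 mg/L. The most abundant was dsvC, a small sulfur carrier protein of sulfite reduction, with 4.14%, 3.71%, 6.29% and 5.79%. Fold differences are on the RPKM + 1 scale, which understates those of low genes.

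At 1 mg/L, 10 genes with a stated function were at least 2-fold higher than in the control. Among them metE, the cobalamin-independent methionine synthase, was at 3.22 RPKM in the control and 27.4 at 1 mg/L, metF, which supplies its methyl donor, at 53.0 and 158, and ahcY, S-adenosylhomocysteine hydrolase, at 174 and 479. The locus of metE holds 2 genes, so the division of reads is uncertain. DVU0606, an ArsR-type regulator, was at 114 and 268 RPKM. A chelatase, DVU0650, was 4.17-fold higher (91.5 and 384 RPKM) and a response regulator, DVU0976, 5.34-fold higher (9.16 and 53.3 RPKM). The zinc resistance-associated gene zraP was at 830.1 and 1788 RPKM.

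The flagellin gene DVU2444, which shares its locus with another gene in the tables, was at 375 RPKM in the control and 2472 at 1 mg/L. FlaG (DVU1442) was at 43.8 and 104 RPKM, and flgM, the anti-sigma factor that holds back flagellin expression, at 317 and 699. Another flagellin gene, DVU2082, chosen after its values were seen, was within 2-fold, at 20.2 and 35.2 RPKM. Among genes with a stated function, those at least 2-fold lower were thiS, a sulfur carrier of thiamine synthesis (7916 and 3553 RPKM), and the DNA-binding protein DVU1744 (12.9 and 5.82 RPKM).

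In all, 50 genes were at least 2-fold higher and 35 at least 2-fold lower at 1 mg/L than in the control, of 2865 genes at 10 RPKM or more in either library. Many of these genes were short or had no stated function, and 23 of the higher and 17 of the lower genes were listed at 0 in 1 of the libraries. Among genes alone in their locus and at least 300 bases long, 10 were higher and 0 lower. The authors' deposited table calls 7 genes higher and 0 lower at q of 0.05 or less, and 6 of the 7 were at least 2-fold higher. The remaining one, DVU0799, chosen after its values were seen, was at 4104 and 4872 RPKM in the authors' deposited table, with a q of 0.00519.

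Several gene groups lay slightly but jointly above or below the control at 1 mg/L. Many members of these groups are neighbours on the chromosome and may vary together, which the random lists do not allow for. The median log2 ratio of 9 ATP synthase genes was 0.61 (percentile 100 of 10000 random lists matched on expression), that of 16 sulfate reduction genes 0.38 (percentile 100), of 55 ribosomal protein genes 0.23 (percentile 100) and of 22 hydrogenase genes 0.19 (percentile 99.99), with no member past 2-fold. For example, sat, the enzyme that activates sulfate, was at 873 and 1231 RPKM, and aprA, a subunit of adenylylsulfate reductase, at 2093 and 2738. The locus of sat holds 3 genes, so the division of reads between them is uncertain. The authors' deposited table does not call sat at any dose. The 32 genes of the flagella list, in which the flagellins have no symbol and are therefore missing, had a median of -0.21 (percentile 0), and 29 of them were below the control. Chaperones and proteases lay at -0.10 (percentile 2.37), with groEL at 785 and 445 RPKM. Iron uptake was at 0.18 (percentile 99.2, 9 measured members) and copper and heavy metal transport at -0.17 (percentile 3.3, 5 members).

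At 50 mg/L, the genes with a stated function that stood highest above the control were iron uptake genes and a stretch of transport genes, DVU2377 to DVU2390. feoB, the ferrous iron permease, was at 57.9 RPKM in the control, 61.0 at 1 mg/L and 1446 at 50 mg/L (24.6-fold), and its neighbour DVU2572, annotated as ferrous iron transport protein A, at 104, 119.8 and 2394. The flavodoxin DVU2680, an electron carrier that holds flavin and no iron, was at 97.51 RPKM in the control and 3026 at 50 mg/L (30.7-fold). Of the 10 genes of the iron uptake list, 9 were at least 2-fold higher, with a median log2 ratio of 3.64 (percentile 100), and the iron-responsive regulator fur (DVU0942) was at 262 and 311 RPKM. Beyond the transporters and the flavodoxin, the 9 hold an AraC-type regulator (DVU2378), a gene annotated as a diguanylate cyclase (DVU0763) and the hypothetical genes DVU0303, DVU0304 and DVU3330. Of these list members, fur, DVU0763, DVU0304 and DVU3330 were chosen after their values were seen. feoB and DVU2572 share a locus in the tables, so the division of reads between them is uncertain. The authors' deposited table gives DVU2572 a q of 0.999 and calls 8 of the list's genes higher.

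The stretch of the chromosome from DVU2377 to DVU2390, positions 2475373 to 2493221 in the deposited tables (genome build not given in the sources used here), was higher as a whole. Its TonB-dependent receptor gene DVU2383, for uptake across the outer membrane, was at 3.69 RPKM in the control, 4.60 at 1 mg/L and 298 at 50 mg/L (63.7-fold). The ABC transporter genes DVU2384 to DVU2387 lay between 1.15 and 1.75 RPKM in the control and between 72.7 and 107 at 50 mg/L. The TonB-ExbB-ExbD-type genes tolQ-1, DVU2389 and DVU2390 were 25.8-fold, 28.2-fold and 16.3-fold higher. DVU2384 to DVU2386 share a locus, as do tolQ-1, DVU2389 and DVU2390, so the division of reads within each locus is uncertain. The extent of the stretch, and its members DVU2377 and DVU2390, were chosen after their values were seen.

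**Figure D1:**
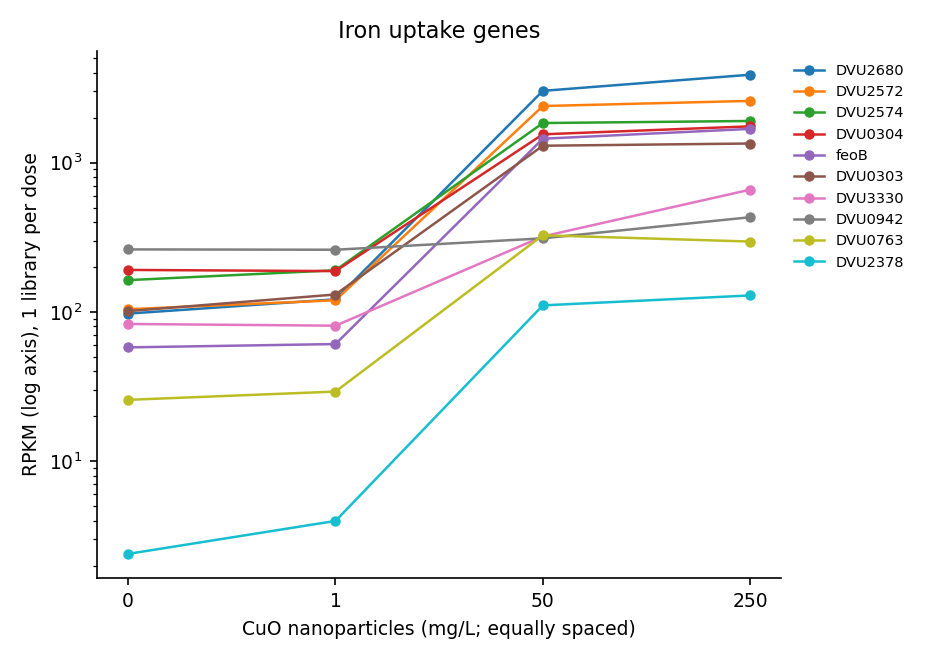
RPKM (log axis) of the 10 genes of the iron uptake list in the 4 libraries, by dose of CuO nanoparticles in mg/L (equally spaced); each point is 1 library and lines join the values of a gene. The control and 1 mg/L libraries lie close together, as in feoB (57.9 and 61.0 RPKM), and the 50 and 250 mg/L libraries lie above them (1446 and 1683 RPKM).

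The flagella list lay below the control at 50 mg/L, with 29 of its 32 genes below it and 10 at least 2-fold lower. The hook gene flgE was at 766 RPKM in the control and 113 at 50 mg/L, flgD at 615 and 113, the hook-associated gene DVU0519 (FlgK) at 243 and 47.8, and DVU0307, a basal body rod gene, at 573 and 83.3. DVU0520 (FlgL) was at 206 and 48.3 RPKM, and DVU1445, a hook-length control gene, at 301 and 52.8. Of these genes, DVU0307 and DVU1445 are not in the list. DVU0519 lies in a locus of 2 genes, so the division of reads is uncertain. In the list 1 gene, flgM, was at least 2-fold higher (1043 RPKM), and the median log2 ratio was -0.74 (percentile 0). The flagellin genes DVU2444 and DVU2082 lay the other way: DVU2444 was at 2078 RPKM, against 375 in the control, and DVU2082, chosen after its values were seen, at 20.2 and 476. The deposited annotation covers only genes at least 2-fold from the control, so a flagellin gene within 2-fold would not be seen. Flagellins are near-identical copies in many bacteria, so reads may be divided between them and their values are uncertain. The 16 genes of the chemotaxis list, which holds no chemoreceptor genes, had a median of -0.18 (percentile 2.35, and -0.37 with equal sums). In it, cheW-1 was at 149.9 and 51.6 RPKM and cheW-2 at 825 and 1480. The chemoreceptor gene DVU0170, outside the list, was at 71.3 and 16.5.

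**Figure D2:**
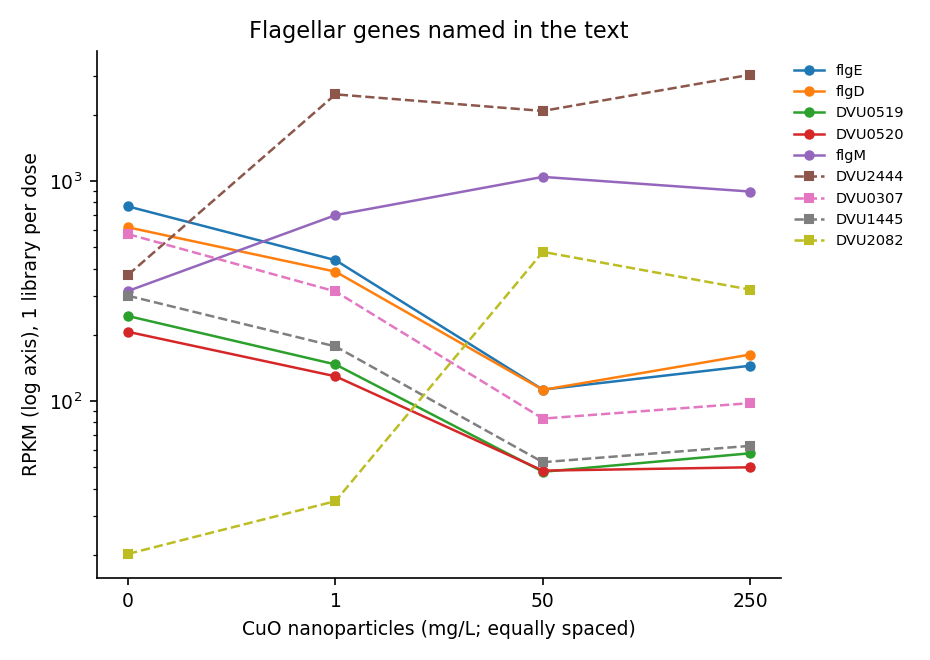
RPKM (log axis) of 9 flagellar genes in the 4 libraries, by dose of CuO nanoparticles in mg/L (equally spaced); each point is 1 library, with solid lines for list members and dashed lines for other genes. The hook gene flgE goes from 766 RPKM in the control to 113 at 50 mg/L, while the flagellin gene DVU2444 goes from 375 to 2078.

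Among the other genes lower at 50 mg/L, hydroxylamine reductase (DVU2543) was at 326 RPKM in the control and 40.9 at 50 mg/L. The EF-hand protein DVU2090 was at 147 and 18.0 RPKM, the membrane protein DVU3251 at 50.8 and 9.15, and the lipoprotein DVU3249 at 68.0 and 17.7. zraP, higher at 1 mg/L, was at 210.0 RPKM at 50 mg/L against 830.1 in the control. The other 4 genes of the copper and heavy metal list were above the control, among them the metal-translocating P-type ATPases DVU3332 (19.8 and 47.0 RPKM) and DVU2324 (53.5 and 86.0) and merP, a metal-binding protein (3024 and 4724). DVU3332 lies in a locus of 3 genes, so the division of reads is uncertain. Another P-type metal ATPase gene, DVU2800 (7.09 and 27.0 RPKM), is not in the list and was chosen after its values were seen. The list's median log2 ratio was 0.64 (percentile 99.5) and its mean, which zraP pulls down, 0.13.

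Most protein-folding and redox genes lay above the control at 50 mg/L, nearly all within 2-fold. The median log2 ratio of 16 chaperone and protease genes was 0.40 (percentile 100; 0.22 with equal sums), with groES at 470.1 and 1220 RPKM and dnaK at 189 and 366. The 21 genes of oxidative stress defence had a median of 0.30 (percentile 96.5; 0.12 with equal sums). The peroxidase-family gene DVU2247 was at 340.0 and 959 RPKM, but sodB, the iron superoxide dismutase, was lower at 178 and 74.0, as was ngr, nigerythrin, at 508 and 220.2.

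Genes of energy metabolism differed in direction at 50 mg/L. sat was at 873 RPKM in the control and 1793 at 50 mg/L, and dsvC at 18348 and 31736, whereas the sulfite reductase genes dsvA (996 and 780.4) and dvsB (888 and 828) were slightly below the control, and the list's median was 0.23 (percentile 88.4; 0.046 with equal sums). The 16 genes from lactate to acetate had a median of -0.22 (percentile 1.04), with 15 below the control, for example glcD, a glycolate oxidase or lactate dehydrogenase subunit gene, at 201 and 134. Hydrogenases had a median of -0.12 (percentile 13.7), with hynB-2 at 11.2 and 3.08. Formate dehydrogenases had a median of -0.35 (percentile 4.59), but 2 of the 5 members lay above the control and the mean was -0.096. The median was -0.17 for transmembrane electron transfer complexes (percentile 2.13), -0.22 for aminoacyl-tRNA synthetases (percentile 0.69) and 0.20 for ATP synthase (percentile 76.5). With equal sums medians were lower, at -0.40 for lactate to acetate, -0.30 for hydrogenases, -0.37 for transmembrane complexes, -0.41 for aminoacyl-tRNA synthetases and 0.011 for ATP synthase. Ribosomal proteins lay at 0.15 (percentile 38.1), a sign that turns with equal library sums (-0.037).

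At 50 mg/L, 101 genes were at least 2-fold higher and 124 at least 2-fold lower, of 2883 considered. The split depends on the scaling: with the libraries set to equal sums it was 85 higher and 171 lower (33.2% higher, against 44.9%), since the median gene then lay at -0.19 in place of -0.01. Of the genes past 2-fold, 17 higher and 21 lower were listed at 0 in 1 of the libraries. Among genes alone in their locus and at least 300 bases long, 35 were higher and 63 lower. The authors' deposited table calls 39 genes higher and 34 lower at q of 0.05 or less, of which 38 and 34 were counted as past 2-fold here. The remaining gene, metE (3.22 and 8.76 RPKM), was past 2-fold but under the limit of 10 RPKM.

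At 250 mg/L, the same iron uptake and transport genes stood above the control. feoB was at 1683 RPKM (28.6-fold over the control), DVU2680 at 3881 (39.4-fold), DVU2383 at 385 (82.4-fold) and fur (DVU0942) at 431. The same 9 members of the iron list were at least 2-fold higher as at 50 mg/L, with a median log2 ratio of 3.62 (percentile 100). The hook genes flgE and flgD were at 145 and 163 RPKM. The flagella list's median was -0.66 (percentile 0; -1.02 with equal sums), with 7 members at least 2-fold lower and flgM at 895, while the flagellin gene DVU2444 was at 3036. The chemoreceptor gene dcrH was at 59.3 RPKM in the control and 12.6 at 250 mg/L and the chemoreceptor gene DVU0700 at 38.2 and 7.80. The chemotaxis list, which leaves out the chemoreceptor genes, had a median of -0.12 (percentile 2.2, and -0.50 with equal sums).

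The ATP synthase genes were higher together at 250 mg/L, with 8 of 9 past 2-fold and a median log2 ratio of 1.46 (percentile 99.99). atpC was at 331 RPKM in the control and 1083 at 250 mg/L, and atpE at 696 and 1968. All 55 ribosomal protein genes were above the control as deposited, with a median of 0.61 (percentile 99.2; 0.23 with equal sums), and 4 were past 2-fold, led by rpmJ at 2794 and 10816 RPKM. Shorter genes tended to have higher ratios in this library: across 1975 genes alone in their locus, Spearman's rho between coding length and log2 ratio was -0.27 at 250 mg/L, -0.23 at 50 mg/L and -0.0028 at 1 mg/L (genes are not independent replicates). Of the 16 sulfate reduction genes, sat (2661 RPKM) and ppaC, which removes the pyrophosphate that sat forms (487 and 1071), were past 2-fold. Neither is called in the authors' deposited table. The list's median was 0.56 (percentile 98.7, and 0.18 with equal sums). Against the 1 mg/L library in place of the control, the 250 mg/L medians were 0.81 for ATP synthase (percentile 98.7), 0.44 for ribosomal proteins (percentile 88.5) and 0.12 for sulfate reduction (percentile 18.25). In that comparison copper and heavy metal transport lay at 0.95 (percentile 99.8), chaperones and proteases at 0.34 (percentile 99.27), hydrogenases at -0.22 (percentile 0.43) and lactate to acetate at -0.36 (percentile 0.02), each farther out than against the control.

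The amino acid list lay on both sides of the control at 250 mg/L. trpB-1, a tryptophan synthase subunit, was at 17.6 RPKM in the control, 46.4 at 50 mg/L and 177 at 250 mg/L, aroA of the shikimate pathway at 115 and 289, and DVU0462, chorismate mutase, at 108 and 269. leuD of leucine synthesis was at 51.4 and 20.9 RPKM, and argD of arginine synthesis, which is not in the list, at 378 and 58.9. Of the 40 measured genes of the amino acid list, 6 were at least 2-fold higher and 1 at least 2-fold lower, and the median was 0.10 (percentile 67.6), turning to -0.27 with equal sums. Apart from trpB-1, the higher genes lie in 1 stretch, DVU0460 to DVU0471, chosen after the values were seen. They are in loci of 2 to 4 genes, where the division of reads is uncertain, and aroA and DVU0462 share a locus. Of the 6, the authors' deposited table calls only trpB-1.

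Hydroxylamine reductase (DVU2543) was at 25.2 RPKM at 250 mg/L, against 326 in the control, and its neighbour DVU2544, an iron-sulfur protein, at 90.0 and 20.8. In the copper and heavy metal list, DVU3332 was at 91.6 RPKM and zraP at 599, with a list median of 0.48 (percentile 91.1; 0.10 with equal sums). groES was at 1044 and DVU2247 at 1032 RPKM, while sodB (55.1) and ngr (189.7) were lower than in the control. The medians of chaperones and proteases (0.25, percentile 86.2) and oxidative stress defence (0.31, percentile 70.3) lay above 0 but at -0.12 and -0.069 with equal sums. Lactate to acetate had a median of -0.15 (percentile 0.97; -0.52 with equal sums), with the lactate permease gene DVU2683 past 2-fold at 97.8 and 202.

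The remaining lists lay near the control as deposited. Equal library sums lower all genes about alike, with the median gene at -0.19 at 50 mg/L and -0.30 at 250 mg/L, and these lists moved with it. At 250 mg/L, hydrogenases had a median log2 ratio of 0.03 (percentile 29), formate dehydrogenases 0.002 (percentile 33.1), aminoacyl-tRNA synthetases 0.02 (percentile 26.2) and transmembrane electron transfer complexes -0.004 (percentile 11.4). With equal sums these were -0.34, -0.34, -0.36 and -0.42. DNA repair and SOS genes lay at -0.02, 0.03 and -0.02 at 1, 50 and 250 mg/L (percentiles 46.9, 80.2 and 42.2), cell division and cell wall genes at -0.04, 0.13 and 0.21 (percentiles 19.7, 91.7 and 87.3), and nitrogen fixation and ammonium uptake genes at 0.12, 0.14 and 0.17 (percentiles 92.1, 77 and 67.8). The nitrogen list holds no gene with a nitrogenase symbol (nifH, nifD or nifK), so it does not describe the nitrogenase genes. With equal sums, the medians at 50 and 250 mg/L turned below 0 or lay further below it, at -0.15 and -0.39 for DNA repair, -0.054 and -0.16 for cell division and -0.046 and -0.20 for nitrogen fixation. At 1 mg/L, oxidative stress defence lay at 0.015 (percentile 56), lactate to acetate at 0.10 (percentile 94.3), chemotaxis at -0.07 (percentile 6.86), formate dehydrogenases at 0.004 (percentile 52.7), transmembrane electron transfer complexes at 0.007 (percentile 57.9), aminoacyl-tRNA synthetases at 0.07 (percentile 95.8) and amino acid biosynthesis at -0.05 (percentile 8.99); the last was at -0.07 at 50 mg/L (percentile 17; -0.26 with equal sums).

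**Figure D3:**
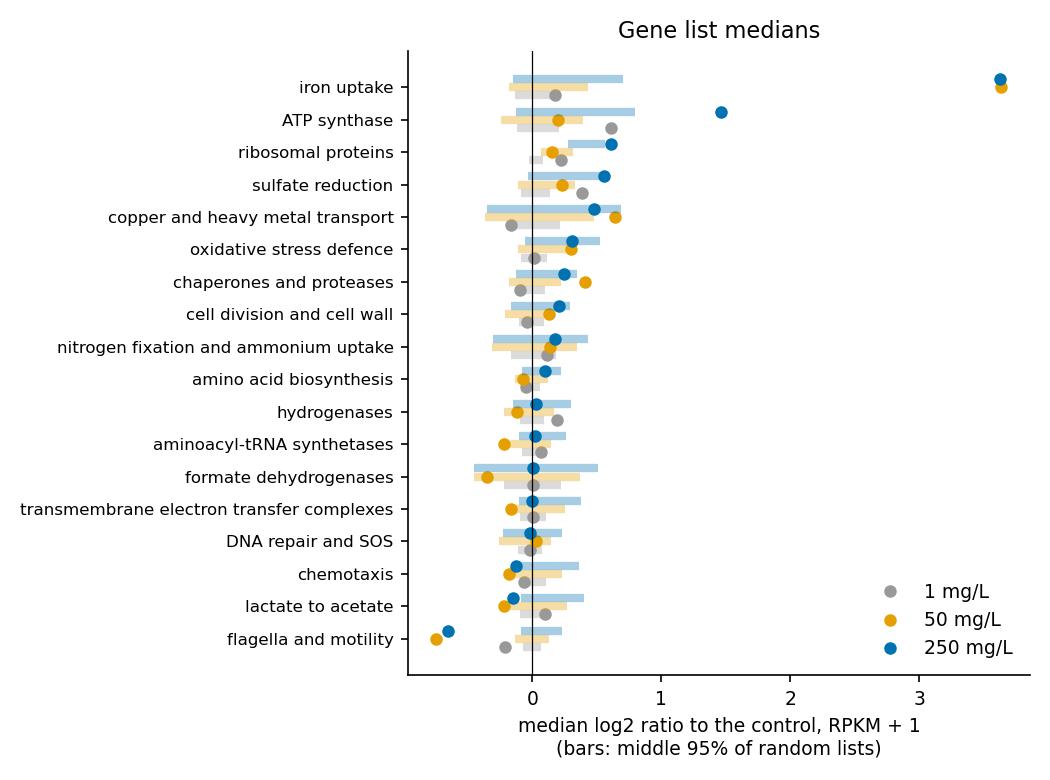
Median log2 ratio to the control (RPKM + 1) of 18 gene lists at 1, 50 and 250 mg/L CuO nanoparticles; points are list medians from 1 library per dose, and bars span the middle 95% of 10000 random lists matched on expression. Iron uptake lies at 3.64 and 3.62 at 50 and 250 mg/L, and flagella and motility at -0.74 and -0.66.

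At 250 mg/L, 175 genes were at least 2-fold higher and 120 at least 2-fold lower, of 2901 considered. With equal library sums the split turned to 109 higher and 270 lower (28.8% higher, against 59.3%), with the median gene at -0.30 in place of 0.07. Centred on the median gene, it did not turn, at 162 higher and 139 lower (53.8% higher). Of the genes past 2-fold, 28 higher and 16 lower were listed at 0 in 1 of the libraries. Among genes alone in their locus and at least 300 bases long, 52 were higher and 68 lower. The authors' deposited table calls 54 genes higher and 41 lower at q of 0.05 or less, of which 53 and 41 were counted as past 2-fold here. The remaining gene, DVU0535, chosen after its values were seen, was at 1.73 and 5.75 RPKM. It was past 2-fold but under the limit of 10 RPKM.

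The 250 mg/L library was also set directly against that of 50 mg/L. Here 93 genes were at least 2-fold higher and 24 at least 2-fold lower at 250 mg/L, of 2869 considered, and 3 genes had opposite calls against the control. trpB-1 was 46.4 RPKM at 50 mg/L and 177 at 250 mg/L, and the gene with the largest difference, the short hypothetical DVU0459 upstream of the aromatic amino acid genes and chosen after its values were seen, 232 and 3614.

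The genes past 2-fold at 50 and at 250 mg/L overlapped. Both doses called 81 genes higher and 78 lower, where independent lists would share 4.99 and 5.19 and simulated libraries without any effect, compared with the same control, shared 14.6 and 33.2. Across 2919 genes the log2 ratios had a Pearson r of 0.717 and a Spearman rho of 0.776 (genes are not independent replicates), with a covariance of 0.725 against a simulated r of 0.501 and covariance of 0.213, a difference in covariance of 0.513. The single control cannot be split, so part of the excess may come from it. The pair that shares no library, 50 mg/L over the control and 250 over 1 mg/L, had an r of 0.463, a rho of 0.677 and a covariance of 0.444, against a simulated r of -0.0031 and covariance of -0.0011, and shared 60 genes higher and 51 lower (4.48 and 3.17 for independent lists, 1.74 and 1.68 simulated).

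Across the 4 libraries, 367 of 2941 genes (12.5%) were higher at each successive dose and 336 (11.4%) lower, where 4 exchangeable values would give 122.5 each way (4.17%). This split turned to 86 and 814 with equal library sums. The libraries were not exchangeable: control and 1 mg/L (Pearson r 0.8955) and 50 and 250 mg/L (0.903) resembled each other most. A single step between these pairs also gives more such genes than 4.17% each way. The counts therefore cannot show a graded response to dose. With steps of at least 1.2-fold, 16 genes went each way. They include sat (873, 1231, 1793 and 2661 RPKM), ppaC and the flavodoxin DVU2680 among the higher, and DVU2543 (326, 243, 40.9 and 25.2), argD, dcrH and sodB among the lower. Of these, sat lies in a locus of 3 genes, and the authors' deposited table calls neither sat nor ppaC at any dose.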

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

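Counts without genes listed at 0, and with genes alone in their locus or also at least 300 bases long, were chosen after the data were seen. Some list medians near 0 changed sign, and the balance of higher and lower genes at 250 mg/L turned, with equal library sums; iron uptake stayed far above 0 and flagella below 0 at 50 and 250 mg/L in every setting run. No replicate could be left out, since each group has 1 library; no paired analysis was possible because no group has a replicate. Counts are called alike when within 1.5 times, and list medians when they move by less than the standard deviation of the random lists' medians. Of 378 recomputed list medians, 330 stayed within that range and 48 moved. Depth is unknown, so it sets no stated limit, and low genes are the least certain. The cause of a difference between settings was not tested except where fewer genes enter by construction.

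Equal library sums gave list medians of ATP synthase 0.011 (50 mg/L) and 1.09 (250 mg/L), DNA repair and SOS -0.15 (50 mg/L) and -0.39 (250 mg/L), amino acid biosynthesis -0.26 (50 mg/L) and -0.27 (250 mg/L) and aminoacyl-tRNA synthetases -0.41 (50 mg/L) and -0.36 (250 mg/L). Under equal sums the medians were cell division and cell wall -0.054 (50 mg/L) and -0.16 (250 mg/L), chaperones and proteases 0.22 (50 mg/L) and -0.12 (250 mg/L), chemotaxis -0.37 (50 mg/L) and -0.50 (250 mg/L) and copper and heavy metal transport 0.10 (250 mg/L). The same scaling put the medians at flagella and motility -0.92 (50 mg/L) and -1.02 (250 mg/L), formate dehydrogenases -0.34 (250 mg/L), hydrogenases -0.30 (50 mg/L) and -0.34 (250 mg/L) and iron uptake 3.45 (50 mg/L) and 3.25 (250 mg/L). Also with equal sums the medians came to lactate to acetate -0.40 (50 mg/L) and -0.52 (250 mg/L), nitrogen fixation and ammonium uptake -0.046 (50 mg/L) and -0.20 (250 mg/L), oxidative stress defence 0.12 (50 mg/L) and -0.069 (250 mg/L) and ribosomal proteins -0.037 (50 mg/L) and 0.23 (250 mg/L). The rest with equal sums were sulfate reduction 0.046 (50 mg/L) and 0.18 (250 mg/L) and transmembrane electron transfer complexes -0.37 (50 mg/L) and -0.42 (250 mg/L). The median gene lay at -0.19 (50 mg/L) and -0.30 (250 mg/L) in this setting. Equal sums also gave 109 genes higher and 270 lower at 250 mg/L, 136 genes lower at both 50 and 250 mg/L, and 86 genes higher and 814 lower at each successive dose.

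A filter at 50 RPKM, with fewer genes entering, gave 30 genes higher and 14 lower at 1 mg/L, 71 and 69 at 50 mg/L and 133 and 68 at 250 mg/L. At 50 mg/L the split thus turned, from 101 higher and 124 lower in the main setting. The filter also gave 48 genes lower at both high doses and 179 lower at each successive dose. With that filter the list medians were DNA repair and SOS 0.12 (250 mg/L), copper and heavy metal transport 0.38 (50 mg/L), formate dehydrogenases -0.040 (50 mg/L) and lactate to acetate 0.19 (1 mg/L). The mean over members in place of the median gave ATP synthase 0.51 (1 mg/L), amino acid biosynthesis 0.011 (1 mg/L) and 0.20 (250 mg/L), aminoacyl-tRNA synthetases -0.13 (50 mg/L) and chaperones and proteases -0.18 (1 mg/L). It also gave copper and heavy metal transport -0.0083 (1 mg/L) and 0.13 (50 mg/L), flagella and motility -0.83 (50 mg/L), formate dehydrogenases -0.096 (50 mg/L) and hydrogenases -0.15 (250 mg/L).

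A 3-fold limit gave 22 genes lower at 1 mg/L, 59 higher and 52 lower at 50 mg/L, and 97 higher and 51 lower at 250 mg/L. Steps of at least 1.2-fold left 16 genes higher and 16 lower at each successive dose. At a q of 0.01 the authors' deposited table calls 35 genes higher and 27 lower at 250 mg/L. Leaving out genes listed at 0 gave 27 higher and 18 lower at 1 mg/L. Genes alone in their locus gave 31 higher and 22 lower at 1 mg/L and 113 higher at 250 mg/L. Those of at least 300 bases gave 10 and 0 at 1 mg/L, 35 and 63 at 50 mg/L, and 52 and 68 at 250 mg/L.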

Other observations

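The length corrections over members with a length were chosen before their results were seen, and so was the rescaling to equal library sums. The tests that leave out the control, that of the dose, the bounds for members without a length, the use of equal sums to weigh these patterns, and the genes named here outside the lists were chosen after.

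thiE-1 (DVU2091) was at 161 RPKM in the control and 103, 78.1 and 56.2 at 1, 50 and 250 mg/L. DVU2092, annotated as ThiF, was at 169, 109.9, 82.6 and 61.4, and thiM at 25.2, 20.6, 16.6 and 11.7. thiS, in a locus shared with thiG, was at 7916, 3553, 5183 and 3674. The EF-hand gene DVU2090, next to thiE-1, was at 147, 74.7, 18.0 and 18.4.

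The phosphate-binding transporter gene DVU2667 was at 16.4 RPKM in the control, 13.0 at 1 mg/L, 73.5 at 50 mg/L and 18.4 at 250 mg/L. metE, at 27.4 RPKM at 1 mg/L, was at 8.76 at 50 mg/L and 3.56 at 250 mg/L, against 3.22 in the control. The P-type metal ATPase gene DVU2800 was at 7.09, 8.32, 27.0 and 10.8. Nearby, DVU2802 (51.5, 51.2, 110 and 132), DVU2803 (50.3, 61.1, 142 and 206) and DVU2804, a metallo-beta-lactamase (58.8, 68.8, 142 and 219), were past 2-fold at both 50 and 250 mg/L. Of the genes next to DVU2800, DVU2799 was past 2-fold at 50 mg/L only (76.4, 91.9, 167 and 132). DVU2801 was within 2-fold at each dose (96.5, 83.6, 85.2 and 73.0). An RNA-binding protein gene, DVU1257, was higher at each dose (1239, 1620, 2999 and 5036).

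The higher iron uptake genes at 50 and 250 mg/L were weighed against 2 technical explanations. A control library low in these genes would put the ratio of 250 to 1 mg/L, which leaves the control out, among random lists, but the list's median log2 ratio there was 3.33. Rescaling to equal sums multiplies each library by 1 factor and so lowers all genes at 250 mg/L about alike (median gene -0.30). It left the list's median over the control at 3.25. This shows only that the difference in library sums is too small to account for the list. The dose itself stays open: 9 members were 2-fold higher at both 50 and 250 mg/L and none at 1 mg/L, but with 1 library per dose, an effect of dose and a difference between those cultures cannot be told apart.

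ATP synthase and ribosomal protein genes were higher at 250 mg/L, where short genes had higher ratios in general. After removal of the trend with coding length, the ribosomal median of 0.642 (46 of 55 members alone in their locus) was 0.397, at percentile 87.29 of random lists, so gene length could account for how far this list stood apart. For ATP synthase this correction was void, because only 77.8% of members are alone in their locus, under the 80% needed; but even with the others set lowest the corrected median was 1.22, above the middle 95% of random lists (upper end 0.678), which argues against length as the whole cause. Equal library sums, which lower all genes about alike, left its median at 1.09. The difference in library sums is thus too small to account for it. The ATP synthase median of 250 over 1 mg/L was 0.813, little above the middle 95% of random lists (upper end 0.757). That is smaller than the 1.46 over the control. The 1 mg/L library also lay above the control (0.61), and the 50 mg/L library less so (0.20). A control partly low in these genes thus stays possible. The dose stays open, with 1 library.

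The flagella list lay below the control at 50 and 250 mg/L, while the flagellin genes DVU2444 and DVU2082 were higher. A control library high in these genes is argued against as the whole cause by the median of 250 over 1 mg/L, which was -0.43 and below the random lists (percentile 0). That median is smaller in size than the -0.66 over the control. The 1 mg/L library also lay below the control (-0.21), so a control partly high in these genes stays possible. The length correction was void here too, with 62.5% of members alone in their locus. Even with the others set highest, the corrected median was -0.325 at 50 mg/L and -0.344 at 250 mg/L, below the middle 95% of random lists (lower ends -0.168 and -0.175), which argues against length as the whole cause. The dose stays open, with 1 library for each.

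In the authors' deposited table, DVU2572 has a q of 0.999 at 50 and at 250 mg/L, at 104 RPKM in the control, 2394 and 2592, while its locus partner feoB (57.9, 1446 and 1683) is called higher at both.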
